A study of Mus musculus with 9 samples.

How the data were processed

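The samples were brain hemispheres of experimentally naive adult male mice, without the cerebellum, from 3 strains: C57BL/6ByJ, BALB/cJ and a strain whose full name, with its line number, stands on the axes of the figures and is shortened in the text to B6By.C. Its name marks it as one that carries BALB/c donor DNA on a C57BL/6By background. Each of the 9 arrays held a pool of 10 hemispheres, with 3 arrays per strain, 30 mice per strain and 90 mice in all, and mice were 11 ± 1 weeks old. Biotin-labelled cRNA was made from 7 µg of total RNA and hybridised to Affymetrix Mouse430_2 arrays, per the labels' protocols. The work was done in 3 batches with every strain in each, per the study's design text, but no label says that a replicate number is a batch number. A pool of hemispheres averages over mice, so the scatter between arrays is that between pools.

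The deposited table holds 1 signal intensity per probe set and array, on a linear scale, and the submitters' processing notes name GCOS and RMA without versions or an order. How background was treated and on which scale arrays were normalized is not recorded. The median intensity per array lay between 15.49 and 15.99, and the log2 intensity ran from 1.824 to 13.1. Repeated values are a feature of the deposited table: 27720 probe sets (61.5%) had 1 value on at least 2 of the 9 arrays, and 1280 (2.84%) had 1 value on all 3 arrays of a strain. Values were compared exactly as deposited, without rounding. The share with 1 value on at least 2 arrays was 74.2% in the dimmest 25% of probe sets by mean level and 40.2% in the brightest 25%, so equal values are most frequent at the low end. The precision of every value is limited by the number of arrays.

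Intensities were taken to log2 with no pseudocount, since all were above 0, and no further normalization was applied. Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. The platform annotation gave 1 gene for 34945 probe sets, several genes for 932 and none for 9160; probe sets with several genes or none carry no gene name here. Symbols were updated by Entrez identifier through the RefSeq annotation of the assembly GRCm38.p6, which held 34741 of the named probe sets. That annotation was used only for names, chromosomes and gene order, because the array table names no genome build, and no coordinates are given. Where a gene had several probe sets, the one with the highest mean over the 9 arrays represented it in gene counts, gene lists and gene order (18193 genes, 18030 with a chromosome).

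A linear model with 1 mean per strain was fitted to all 9 arrays with limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom, prior degrees of freedom 4.823). Each of the 3 strain pairs was compared with the moderated, two-sided test of limma, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. Standard errors (SE) are those of the log2 difference; SD is over 3 arrays. Chromosomes were compared with a two-sided Fisher's exact test, and windows of 50 consecutive genes with 10000 permutations of the calls over the genes. For runs of BALB/cJ-like genes, each gene with a probe set called between the parental strains was placed by its called probe set with the lowest p-value, and counted as BALB/cJ-like where B6By.C was closer to BALB/cJ. Arrays were simulated as unchanged groups around 1 mean (100 draws) to show what the shared C57BL/6ByJ arrays give with no effect. The model was tested on simulated data with independent noise for BALB/cJ against C57BL/6ByJ. At each size 50 probe sets among 45037 were changed, all of them with a mean level at or above the median. The model called 46% of those changed by 0.5 on the log2 scale, 94% of those changed by 1, and 100% of those changed by 1.5 or 2. Along with them it called 7 unchanged probe sets, and 15 between B6By.C and BALB/cJ. All sizes were planted together in the BALB/cJ arrays, which eases the adjusted threshold for each. No change was planted between B6By.C and C57BL/6ByJ, so these rates do not describe that comparison. Recovery of dimmer probe sets was not simulated.

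A set of 29 gene lists (brain cell types, transmitter systems, channels, ethanol and aldehyde metabolism, immediate early genes, hormone and immune responses, and energy and redox genes) was fixed before the data were examined. Each list was tested with camera from limma, on representative probe sets, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the 29 lists of a comparison. On simulated data with 1 list shifted by 0.3 on the log2 scale, the preset correlation also called 1 unshifted list. Named genes also followed a rule fixed before the data were examined. It took the 8 genes with the largest change each way between the parental strains and the 5 largest each way between B6By.C and BALB/cJ. These had to be single-symbol representative probe sets with an adjusted p under 0.05, array values that did not overlap between the strains, and a mean in the higher strain of at least the median of all probe sets (3.968). It added up to 4 called members of each list and every probe set of Grm7, a metabotropic glutamate receptor gene. Genes named outside the rule are marked as chosen after their values were seen.

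Whether replicate numbers pair the arrays was checked on deviations from the strain means. Same-numbered arrays of different strains correlated at 0.5186 to 0.5416 for number 1, 0.1469 to 0.1801 for number 2 and 0.2054 to 0.2662 for number 3, and the 18 pairs with different numbers lay between -0.4579 and 0.1528. All 9 same-number correlations were above 0.1, but so was the highest pair with different numbers. Those of numbers 1 and 3 lay above every pair with different numbers, while number 2 overlapped them (0.1469 against 0.1528). Because replicate 1 stood apart in each strain, arrays 2 and 3 share part of a deviation whatever their numbers. Pairing is therefore clear for number 1 and less certain for numbers 2 and 3. This pairing comes from the data, with the 3 batches of the design text as its possible origin. A second model with the replicate number as a block (4 residual degrees of freedom) is given beside a result where it changes a call or moves a count by more than 1.5 times.

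Other settings were median centring of arrays, quantile normalization, leaving out the dimmest 40% of probe sets (mean log2 under 3.48) or the less specific probe sets ending in _x_at or _s_at, fitting only the strains compared, an intensity trend in the prior variance, array weights, each array left out in turn, a threshold of 0.01, and the median over the probe sets of a gene for the lists. Sex could not be checked from the arrays, because the probe sets of the sex-linked genes read near the median of all probe sets or below it on all 9 arrays.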

Results

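Transcript levels were measured in pooled brain hemispheres of 3 mouse strains, with 3 arrays per strain and 10 hemispheres per array. C57BL/6ByJ and BALB/cJ are inbred parental strains. The strain shortened here to B6By.C, with its full name on the figures' axes, lies on the C57BL/6By background and has a donor contribution from BALB/c by its name, so its arrays show which of the parental differences travel with that contribution. Across all probe sets, the median correlation between arrays was 0.993 within strains, 0.9929 between C57BL/6ByJ and B6By.C, 0.9906 between C57BL/6ByJ and BALB/cJ, and 0.9882 between BALB/cJ and B6By.C. The first 3 principal components held 29.08%, 25.74% and 17.96% of the variance. B6By.C replicate 3 had the narrowest spread of values (interquartile range 2.731 on the log2 scale) and the lowest mean correlation with its own strain (0.988).

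The comparison of BALB/cJ with C57BL/6ByJ asks which brain transcripts differ between the parental strains. Among the genes named by rule, the largest increase in BALB/cJ was that of Cap1, an actin-binding protein associated with adenylyl cyclase (chromosome 4), at 8.49 ± 0.295 against 4.38 ± 0.141 log2 intensity (SD, n = 3 each), or 17.3-fold (limma, Benjamini-Hochberg adjusted p = 1.76e-07). Baiap2l1, which encodes a membrane-bending adaptor of the actin cytoskeleton (chromosome 5), measured 6.29 ± 0.119 against 3.21 ± 0.058 (adjusted p = 7.4e-08), and Tmem87a (chromosome 2) was 7.00-fold higher (adjusted p = 5.98e-07). In the other direction, Prune2 (chromosome 19) measured 3.73 ± 0.104 in BALB/cJ against 9.61 ± 0.0466 in C57BL/6ByJ (adjusted p = 1.39e-10). Rpgrip1, a ciliary protein best known from photoreceptors (chromosome 14), measured 3.19 ± 0.127 against 8.93 ± 0.0375 (adjusted p = 8.91e-11). In Baiap2l1, Prune2 and Rpgrip1 the lower strain lay below the median of all probe sets (3.968), where signal is close to background, so no fold is given for them; in Cap1 and Tmem87a it lay a little above that median.

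Further genes rose in BALB/cJ. Erdr1, annotated to the X chromosome, was 4.36-fold higher, Gnb1, a G protein beta subunit on chromosome 4, was 3.99-fold higher, and Kcnj9, a G protein-gated inward rectifier potassium channel subunit on chromosome 1, was 3.25-fold higher. Hddc3 (chromosome 7) was 3.06-fold higher, and Alad, an enzyme of haem synthesis on chromosome 4, was 2.96-fold higher. Among the genes that fell were the transcription factor gene Sox11 (chromosome 12, 8.54-fold), Pdxdc1 (chromosome 16, 6.88-fold), 1500004A13Rik (chromosome 3), Pttg1, which encodes securin of the cell cycle (chromosome 11, 4.81-fold), the long noncoding RNA gene Rmst (chromosome 10) and a probe set annotated to Mir1931 (chromosome 10, 4.16-fold). In BALB/cJ, 1500004A13Rik (2.53) and Rmst (3.90) lay below the median of all probe sets, so no fold is given for them. Adjusted p-values of these 11 genes ran from 2.94e-07 for Pttg1 to 0.000399 for Kcnj9 (limma). Other probe sets of a gene did not always move with the named one. Cap1, Baiap2l1 and Alad each had 1 other probe set, called in the same direction, and both other probe sets of Pttg1 were called lower. Of the 3 other probe sets of Prune2 and the 5 of Sox11, none was called the same way and 1 each was called in the opposite direction. Pdxdc1 and Kcnj9 each had 1 called the same way and 1 the opposite way, and none of the 3 other probe sets of Rpgrip1 was called. Erdr1, Hddc3 and Rmst each had 1 other probe set, which was not called. Gnb1 and 1500004A13Rik each had 2 others, 1 of them called the same way. Tmem87a and Mir1931 had no other probe set.

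**Figure D1:**
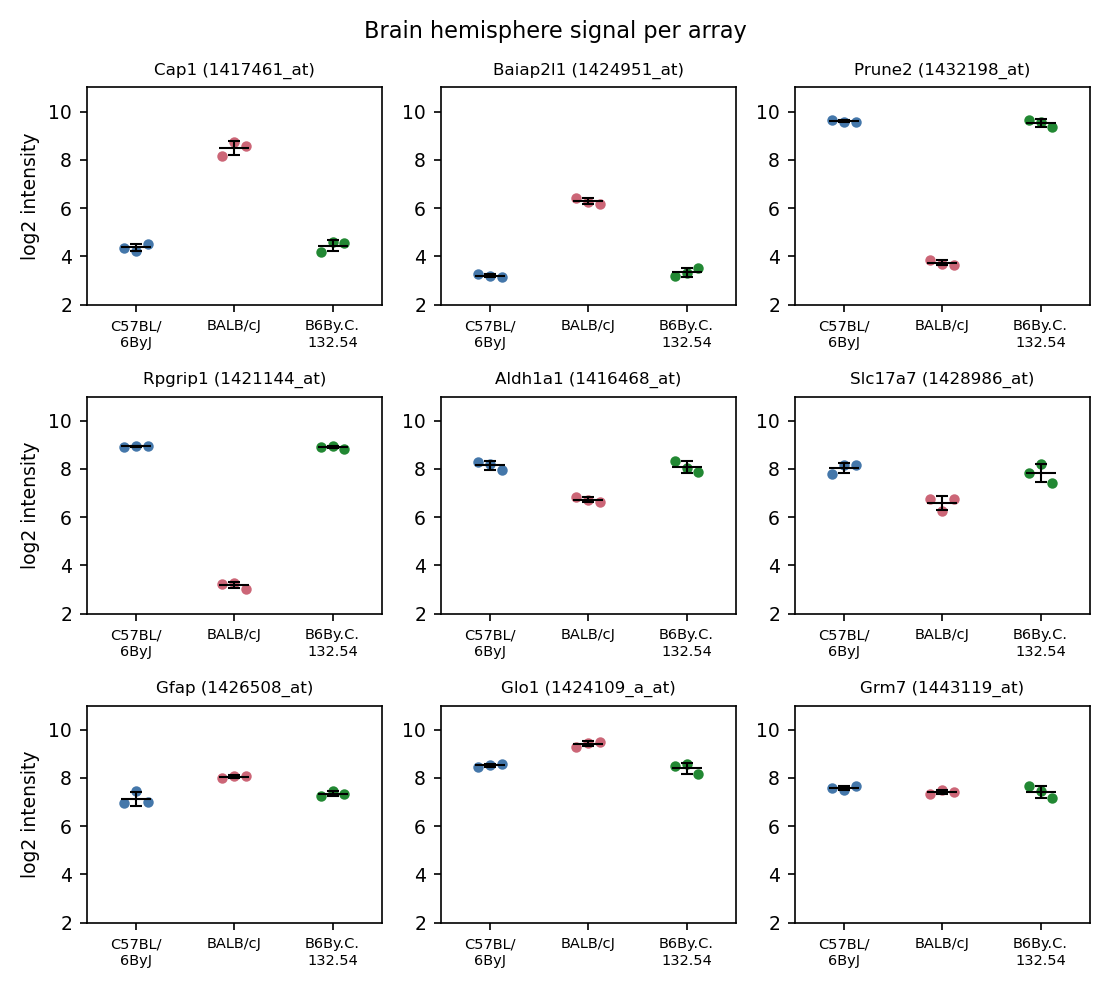
Log2 intensity of 9 probe sets on every array, by strain; points are single arrays (n = 3 per strain, each a pool of 10 hemispheres), and black bars give the mean ± SD. For Cap1, Baiap2l1, Prune2, Rpgrip1, Aldh1a1, Slc17a7, Gfap and Glo1 the BALB/cJ arrays lie apart from the C57BL/6ByJ arrays while the B6By.C arrays lie near the latter, and the brightest Grm7 probe set lies near 7.5 in all 3 strains.

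Among the cell type lists, Gfap, the intermediate filament of astrocytes, rose 1.89-fold in BALB/cJ (8.06 ± 0.0567 against 7.14 ± 0.286, SD, n = 3; limma adjusted p = 0.00393), and both of its other probe sets were called higher. It was the 1 called gene of 11 astrocyte markers; over the list alone 1 rose and 1 fell. The complement genes C1qc and C1qb, expressed by microglia, fell by 0.75 and 0.75 on the log2 scale (limma adjusted p = 0.00943 and 0.0193), and the other 11 measured microglia and complement markers did not pass. C1qa of the same list, named after its values were seen, went the other way (0.17 ± 0.101 higher, SE) and was not called (limma adjusted p = 0.831). Neither of the 2 other probe sets of C1qb was called, and C1qc had no other probe set. Cldn5, a tight junction gene of brain endothelium, fell by 0.54 (limma adjusted p = 0.0466), 1 of 11 endothelial and pericyte markers. It had no other probe set. The myelin gene Mal passed only with the replicate block (-0.44; limma adjusted p = 0.201 without it and 0.0349 with it), and was named after its values were seen. Without the block, the 12 neuron markers, 13 oligodendrocyte and myelin markers, 6 oligodendrocyte precursor markers, 10 choroid plexus and ependyma markers, 9 meningeal and fibroblast markers and 8 cerebellum markers held no called member, with 1 cerebellum marker higher over the list alone, and none of the cell type lists passed camera (adjusted p of 0.1 or higher). The Cldn5 call was lost without any 1 of the 6 arrays compared (adjusted p from 0.0596 without BALB/cJ replicate 3 to 0.213 without C57BL/6ByJ replicate 2) and without B6By.C replicate 2 or 3 (0.0511 and 0.0583). The C1qc call was lost without C57BL/6ByJ replicate 2 (0.0613), and the C1qb call without C57BL/6ByJ replicate 1 or 2 (0.0526 and 0.101) or BALB/cJ replicate 1, 2 or 3 (0.0911, 0.0761 and 0.0505).

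Among the transmission and channel lists, single members were called. Slc17a7, the vesicular glutamate transporter of cortical neurons, fell by 1.45 ± 0.198 (SE) on the log2 scale (limma adjusted p = 0.00272), 1 of 17 synaptic vesicle genes (camera adjusted p = 0.172 for the list; adjusted p = 0.72 with an estimated correlation). The NMDA receptor subunit gene Grin2b fell by 1.11 ± 0.13 (limma adjusted p = 0.000914) and the kainate receptor subunit gene Grik1 was lower as well (limma adjusted p = 0.00577), at 3.41 ± 0.17 against 4.45 ± 0.326 (SD), the former below the median of all probe sets; these were the 2 called genes of 16 ionotropic glutamate receptors, 3 over the list alone, and neither was joined by another of its probe sets. This list did not pass camera (adjusted p = 0.0899; adjusted p = 0.72 with an estimated correlation). Maob, which degrades monoamines, fell by 0.61 ± 0.0965 (limma adjusted p = 0.00818) as the 1 called gene of 16 dopamine and striatal signalling genes. Of 25 voltage-gated and inward rectifier channels, Kcnj9 and the glial channel gene Kcnj10 rose, the latter by 0.67 ± 0.116 (limma adjusted p = 0.0144). The Kcnj10 call was lost without C57BL/6ByJ replicate 3 (adjusted p = 0.0683) or BALB/cJ replicate 1, 2 or 3 (0.0527, 0.0724 and 0.0726). Slc17a7, Maob and Kcnj10 had no other probe set, so each of these calls rests on 1 probe set. No member of the metabotropic glutamate receptor, GABA, serotonin and noradrenaline, acetylcholine, or opioid and neuropeptide lists was called without the replicate block; with it, the neuropeptide gene Nts was lower (-0.50; limma adjusted p = 0.0825 without the block and 0.0451 with it). Adjusted over the list alone, 1 GABA system gene and 1 neuropeptide gene were lower.

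Of the genes of alcohol and aldehyde metabolism, 2 were called. Aldh1a1, which oxidises retinaldehyde and other aldehydes (chromosome 19), fell by 1.41 ± 0.132 on the log2 scale (6.73 ± 0.114 against 8.14 ± 0.174, SD, n = 3; limma adjusted p = 0.000182), and Aldh7a1 (chromosome 18) fell by 0.90 ± 0.13 (limma adjusted p = 0.00417), while neither of the 2 other probe sets of Aldh7a1 was called. Aldh1a1 had no other probe set. Aldh1a1 and Aldh7a1 were the 2 called genes of 18 in the alcohol and aldehyde metabolism list, also over the list alone. Members of this list were lower as a set than other genes (median -0.0669 and mean -0.2 on the log2 scale). Aldh1a1 and Aldh7a1 lay far below that median, so this may rest largely on them, and the list was not tested without them. Camera from limma gave an adjusted p of 0.00474, and 0.496 with an estimated correlation. The call of this alcohol and aldehyde metabolism list was lost without BALB/cJ replicate 3 (adjusted p = 0.104) and with the median over the probe sets of a gene (0.161). Glo1, which detoxifies methylglyoxal (chromosome 17), rose 1.87-fold (limma adjusted p = 0.00178) with 2 of its 3 other probe sets, as the 1 called gene of 18 glutathione and oxidative stress genes, 2 over the list alone. With the replicate block Gsr was called higher as well (0.54; limma adjusted p = 0.087 without the block and 0.0313 with it). The 15 immediate early genes were higher as a set in BALB/cJ (median 0.219 and mean 0.261 on the log2 scale; camera from limma, adjusted p = 0.00219; adjusted p = 0.72 with an estimated correlation), although none was called, over all probe sets or over the list alone (Junb was called with the replicate block, adjusted p = 0.0261). Junb measured 0.63 ± 0.208 higher and Egr2 0.54 ± 0.17 higher (SE; limma adjusted p = 0.347 and 0.291). They were named after their values were seen. The blood cell, pituitary hormone, sex-linked, glucocorticoid response, MHC and antigen presentation, interferon response, oxidative phosphorylation and circadian clock lists held no called member, also over the list alone, and did not pass camera (adjusted p of 0.31 or higher). For the astrocyte, oligodendrocyte precursor, meningeal, dopamine, acetylcholine and interferon lists, which did not pass, the median, the mean and the test differed in sign.

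In all, 644 of 45037 probe sets were called between BALB/cJ and C57BL/6ByJ, 229 higher and 415 lower in BALB/cJ, and 80 and 163 of these differed at least 2-fold. By representative probe set, 241 of 18193 genes were called, 82 higher and 159 lower; with the replicate block these were 362 genes, 126 higher and 236 lower. At an unadjusted p under 0.05 there were 3416 probe sets, where 2251.8 are expected by chance. Without C57BL/6ByJ replicate 2 the count was 410. No chromosome held more or fewer called genes than the others after adjustment (Fisher's exact test, lowest adjusted p = 0.0846, for chromosomes 4 and 15).

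B6By.C against C57BL/6ByJ asks what the BALB/c contribution changes on the common background. The lowest p-value belonged to Chchd4 (chromosome 6, named after its values were seen), which encodes a protein of the mitochondrial import and folding pathway in the intermembrane space. It measured 6.39 ± 0.181 in B6By.C, 7.41 ± 0.178 in C57BL/6ByJ and 6.26 ± 0.126 in BALB/cJ (SD, n = 3 each). Its difference of -1.02 ± 0.123 (SE) between B6By.C and C57BL/6ByJ did not pass (limma adjusted p = 0.228, and 0.135 with the replicate block). Grm7, the metabotropic glutamate receptor 7 gene on chromosome 6, was measured by 3 probe sets. The brightest read 7.42 ± 0.257 in B6By.C, 7.42 ± 0.0758 in BALB/cJ and 7.59 ± 0.0816 in C57BL/6ByJ, and the middle one read 4.36 ± 0.0881, 4.41 ± 0.114 and 4.44 ± 0.0545; neither was called in any comparison. The dimmest was higher in both B6By.C (3.24 ± 0.129) and BALB/cJ (3.21 ± 0.225) than in C57BL/6ByJ (2.75 ± 0.15). All 3 means lie below the median of all probe sets, and neither difference passed (limma adjusted p = 0.915 and 0.173). With the replicate block, its BALB/cJ difference passed (limma adjusted p = 0.0348) and its B6By.C difference did not (0.658).

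No probe set was called between B6By.C and C57BL/6ByJ by limma, with or without the replicate block. At an unadjusted p under 0.05 there were 1751 probe sets, fewer than the 2251.8 expected by chance, and 3349 with the replicate block. The median SE of a log2 difference was 0.11. Since recovery was not simulated for this comparison, the absence of calls does not show that no probe set differs. Interferon response genes were higher as a set in B6By.C (16 genes, median 0.134 and mean 0.124 on the log2 scale; camera from limma, adjusted p = 0.00157; adjusted p = 0.69 with an estimated correlation). None of the 16 was called, and 12 of them had mean levels under 5 in both strains. With the replicate block, camera also placed the neuron, oligodendrocyte and myelin, endothelial and pericyte, GABA system, dopamine and striatal signalling, channel and immediate early gene lists lower (adjusted p between 0.0466 and 0.0497). None of these 7 passed with the block once the dim probe sets were left out (adjusted p of 0.131 or higher), where only the interferon response list did (0.0344). Without the block none of the 7 passed either (0.088 to 0.166), and with an estimated correlation their adjusted p ran from 0.69 to 0.752. The other 21 lists passed in neither model, and no list held a called member, also over the list alone. The median, the mean and the test differed in sign for the choroid plexus, blood cell, cerebellum, and serotonin and noradrenaline lists.

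B6By.C against BALB/cJ, which shares the BALB/cJ arrays with the parental comparison, gave nearly its mirror image. Prune2 (9.52 ± 0.158 against 3.73 ± 0.104, SD, n = 3 each) and Rpgrip1 (8.90 ± 0.0481 against 3.19 ± 0.127) were higher in B6By.C, as were Sox11 8.12-fold, Pdxdc1 6.23-fold and Pttg1 4.67-fold (limma adjusted p between 9.45e-11 and 2.65e-05). Baiap2l1 was lower (3.34 ± 0.171 against 6.29 ± 0.119), and so were Cap1 16.5-fold, Tmem87a 6.71-fold, Kcnj9 4.65-fold and Gnb1 4.55-fold (limma adjusted p between 1.17e-07 and 6.02e-05). Aldh1a1 was 2.54-fold and Aldh7a1 1.64-fold higher (limma adjusted p = 0.000294 and 0.0211), Slc17a7 2.36-fold and Grin2b 2.02-fold higher (0.0088 and 0.00191), Grik1 higher over a BALB/cJ signal below the median (0.0127), and C1qc 1.78-fold and C1qb 1.84-fold higher (0.00475 and 0.00674). Gfap was 1.63-fold, Kcnj10 1.58-fold and Glo1 2.03-fold lower (limma adjusted p = 0.0238, 0.016 and 0.000776). Called in this comparison, but between the parental strains only with the replicate block (Nts and Gsr) or not at all (Rgs5), were the neuropeptide gene Nts (0.58 higher on the log2 scale, limma adjusted p = 0.0384), the pericyte gene Rgs5 (1.47-fold lower, 0.0361) and the glutathione reductase gene Gsr (1.56-fold lower, 0.0378). None of the 3 other probe sets of Rgs5, nor the 1 other of Gsr, was called, and Nts had no other probe set.

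Several of these smaller calls were lost when 1 array was left out, although the differences kept their sign and much of their size under all settings (0.48 to 0.67 for Nts, -0.63 to -0.46 for Rgs5, -0.75 to -0.51 for Gsr, 0.59 to 0.79 for Aldh7a1). The Aldh7a1 call was lost without BALB/cJ replicate 1, 2 or 3 (limma adjusted p = 0.101, 0.0614 and 0.0758) or B6By.C replicate 2 (0.0675), and that of Grik1 without BALB/cJ replicate 1 or 2 (0.0656 and 0.0821) or B6By.C replicate 1 (0.0565). That of Gfap was lost without BALB/cJ replicate 1, 2 or 3 (0.0659, 0.123 and 0.113) or B6By.C replicate 1 or 3 (0.0988 and 0.081), and that of Kcnj10 without BALB/cJ replicate 1, 2 or 3 (0.0562, 0.0821 and 0.0811). Leaving out C57BL/6ByJ replicate 2 or 3, any BALB/cJ array, or B6By.C replicate 1 or 3 ended the call of Rgs5 (limma adjusted p from 0.0568 to 0.176). Nts was lost without any 1 array except BALB/cJ replicate 2 (0.0609 to 0.162), and Gsr without any 1 array except C57BL/6ByJ replicate 3 and BALB/cJ replicate 1 (0.0511 to 0.137).

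Immediate early genes, which respond to neuronal activity within minutes, were lower as a set in B6By.C than in BALB/cJ (15 genes, median -0.448 and mean -0.39 on the log2 scale; camera from limma, adjusted p = 3.38e-06; adjusted p = 0.649 with an estimated correlation). None was called over all probe sets, 3 (Junb, Npas4 and Btg2) were called with the replicate block, and 7 were lower when adjusted over the list alone, led by Junb (-0.90 ± 0.208, SE; adjusted p = 0.0182 over the list alone) and Npas4 (-0.83 ± 0.232; 0.0215), with Btg2, Dusp1, Egr2, Fos and Fosb. Interferon response genes were higher (median 0.159; camera from limma, adjusted p = 0.00134), with Trim30a (0.57 ± 0.122; 0.0105 over the list alone) and Ifit3 (0.69 ± 0.198; 0.042) called over the list alone, and Trim30a over all probe sets with the replicate block (adjusted p = 0.0432, against 0.0509 without it). The BALB/cJ mean of Trim30a (3.904) lay below the median of all probe sets (3.968). With an estimated correlation the camera adjusted p of the interferon list was 0.649. Tyrobp and the members of these 2 lists were named after their values were seen. Microglia and complement markers were higher (adjusted p = 0.0232; 2 called, 3 over the list alone, and 3 with Tyrobp in the model with the replicate block), the channel list was lower (0.0136; 2 called), and glutathione and oxidative stress genes were lower (0.0175; 2 called, 3 over the list alone). On the log2 scale the medians of these 3 lists were 0.0656, -0.083 and -0.0926, and the means 0.169, -0.2 and -0.167. Their called members lay far beyond these medians (C1qc 0.83 and C1qb 0.88, Kcnj9 -2.22 and Kcnj10 -0.66, Glo1 -1.02 and Gsr -0.64). Each list result may therefore rest largely on its called members, and the lists were not tested without them. With an estimated correlation the camera adjusted p of these 3 lists was 0.752, 0.649 and 0.649. Without B6By.C replicate 3 none of these 3 passed (0.0838, 0.124 and 0.0838), which left the immediate early and interferon lists. With the dim probe sets left out, only the immediate early genes and the microglia and complement markers (camera adjusted p = 0.0316) still passed, so the interferon list lost its call. The other 24 lists did not pass camera (0.113 or higher). Over the list alone, 1 endothelial marker, 1 GABA system gene and 1 dopamine and striatal signalling gene were also higher. The median, the mean and the test differed in sign for the endothelial, metabotropic glutamate receptor, GABA, serotonin and synaptic vesicle lists.

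In total 575 probe sets were called between B6By.C and BALB/cJ by limma, 321 higher and 254 lower in B6By.C, and 138 and 103 of these differed at least 2-fold. The balance turned without B6By.C replicate 2, which left 237 higher and 265 lower (52.8% lower, against 44.2% with all arrays). By representative probe set, 201 genes were called, 107 higher and 94 lower, and 319 genes with the replicate block, 169 higher and 150 lower. At an unadjusted p under 0.05 there were 3378 probe sets.

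Set against the parental difference, B6By.C stood with C57BL/6ByJ. Of the 644 probe sets called between the parental strains, 632 (98.1%) were closer to C57BL/6ByJ in B6By.C, and 502 were also called, with the opposite sign, between B6By.C and BALB/cJ. Both comparisons share the BALB/cJ arrays on which the 644 were picked, and the overlap that this sharing gives was not simulated. The median ratio of the B6By.C change to the BALB/cJ change, both against C57BL/6ByJ, was 0.0675. The other 12 probe sets were closer to BALB/cJ. They comprised Chchd4 and Isy1 (0.47 higher in BALB/cJ and 0.41 higher in B6By.C), both on chromosome 6, Zw10 and Nxpe4 on chromosome 9, Arrdc1 on chromosome 2, Slc35a5 on chromosome 16, Fam204a on chromosome 19 and 5 probe sets without a gene name, all listed after their values were seen. The largest of the 12 differences was that of a probe set without a gene name, at 5.23 ± 0.299 in C57BL/6ByJ, 3.48 ± 0.0989 in BALB/cJ and 3.73 ± 0.514 in B6By.C (SD, n = 3 each). Since limma called no probe set between B6By.C and C57BL/6ByJ, none could be called the same way in both strains against C57BL/6ByJ. For the same reason none could be called in B6By.C against both other strains in one direction. These absences add nothing to that result.

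**Figure D2:**
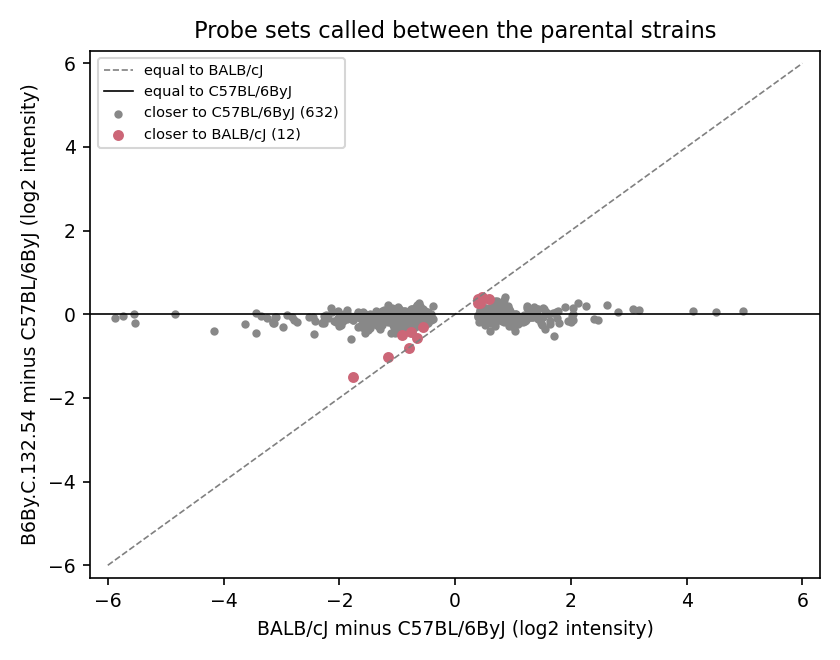
Each point is 1 of the 644 probe sets called between BALB/cJ and C57BL/6ByJ, with the BALB/cJ difference on the horizontal axis and the B6By.C difference on the vertical axis, both against C57BL/6ByJ in log2 intensity. The 632 grey points lie closer to the line of no difference from C57BL/6ByJ, and the 12 red points lie closer to the dashed line of equality with BALB/cJ.

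Across probe sets, which are not independent replicates, the fold changes of both strains against C57BL/6ByJ correlated at 0.33. Both share the C57BL/6ByJ arrays. Simulated unchanged strains gave a correlation of 0.4993 (0.4894 to 0.5116 over 100 draws) and a covariance of 0.007983 (0.007698 to 0.008252), beside an observed covariance of 0.009428, a difference of 0.001445. The simulation drew arrays independently and leaves out the shared deviations of same-numbered arrays, and 3 control arrays cannot be split into groups of 2.

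Along the chromosomes, a run of BALB/cJ-like genes in B6By.C was looked for after the data were seen. With the replicate block, Nfu1, Isy1, Chchd4, Frmd4b, Cntn6 and the dimmest probe set of Grm7 were neighbours on chromosome 6 among the 600 genes called between the parental strains, and each was closer to BALB/cJ in B6By.C. The B6By.C change was 0.866 to 1.06 of the BALB/cJ change in these 6 genes. Nat8f4 before them (0.33) and Ogg1 after them (-0.068) were closer to C57BL/6ByJ, as was Grin2b farther along the chromosome. No run of 6 arose in 10000 permutations of the gene order (permutation p = 1e-04, the smallest they can give). With the dim probe sets also left out, the run lost Grm7 and gained Aak1 at its other end. Without the block the longest runs held 2 genes, Isy1 and Chchd4 on chromosome 6 and Nxpe4 and Zw10 on chromosome 9 (permutation p = 0.0645), and none of the 6 genes was called between B6By.C and C57BL/6ByJ in either model. Other bright probe sets of Isy1 (ratio -0.177), Frmd4b (0.134) and Grm7 (-0.212) did not share the change, while that of Nfu1 did (1.02).

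**Figure D3:**
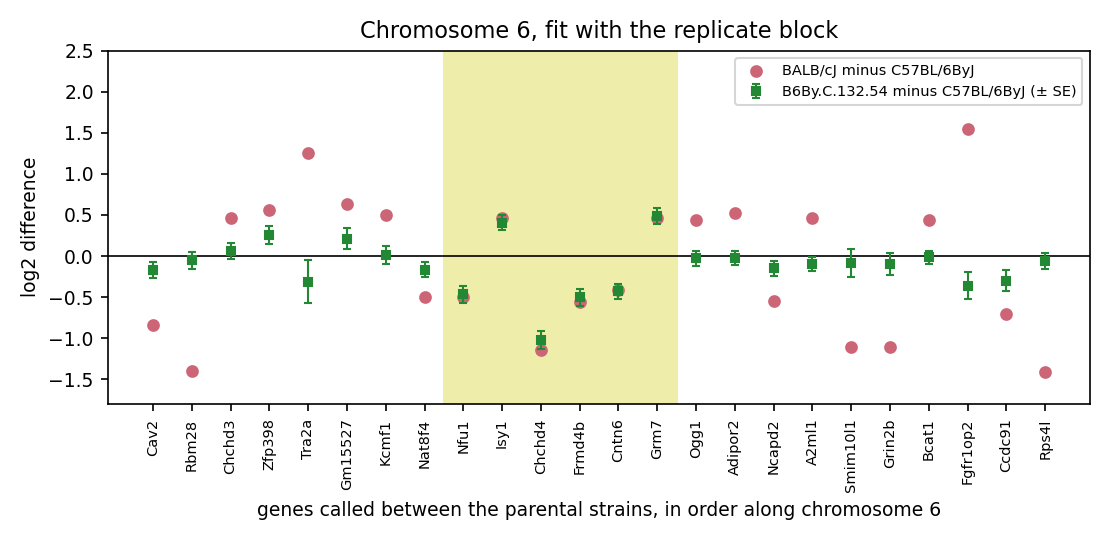
Log2 differences from C57BL/6ByJ in BALB/cJ (red) and B6By.C (green, ± SE) for each gene of chromosome 6 called between the parental strains in the model with the replicate block, in chromosome order (n = 3 arrays per strain). The shaded stretch holds the 6 genes from Nfu1 to Grm7, where both strains differ from C57BL/6ByJ by similar amounts.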

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

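Chosen after the data were seen were the settings that left out all arrays numbered 1 or combined the replicate block with the filter on dim probe sets, and the test of runs along chromosomes. The 644 probe sets called between BALB/cJ and C57BL/6ByJ became 410 to 706 with 1 array left out (lowest without C57BL/6ByJ replicate 2), 369 at a threshold of 0.01, 970 with the block and the dim filter, and 309 without the arrays numbered 1. The 575 of B6By.C against BALB/cJ became 391 to 514 with 1 array left out, 354 at 0.01 and 276 without the arrays numbered 1. Array weights gave 918 and 601 in place of 644 and 575. A stricter threshold makes fewer calls by construction. Leaving out an array usually made fewer calls too, but without B6By.C replicate 3 the 644 rose to 706. The cause of the gains was not tested. With the replicate block the counts were 953, 0 and 834, and all 644 and 575 probe sets were among them. B6By.C against C57BL/6ByJ gave 0 under every setting, so the planned tests of its chromosomes and windows of called genes had no value. The correlation of fold changes ran from 0.2585 to 0.4166 with 1 array left out. Gene lists called by camera with a preset correlation numbered 2, 1 and 5 in the order BALB/cJ and B6By.C against C57BL/6ByJ, then B6By.C against BALB/cJ. With 1 array left out they were 1 to 4, 1 to 3 and 2 to 5. Between the parental strains the 1 came without BALB/cJ replicate 3, which lost the alcohol and aldehyde list, and in the last comparison the 2 came without B6By.C replicate 3. The estimated correlation left 0 in each, and the median over the probe sets of a gene left 1 (losing the same list), 1 and 3. For B6By.C against C57BL/6ByJ the replicate block gave 8, the block with the dim filter 1, and leaving out the arrays numbered 1 gave 4. For B6By.C against BALB/cJ the dim filter left 2 and the dim filter with the block left 3; apart from the estimated correlation, the cause of these changes was not tested. The longest BALB/cJ-like run held 2 genes (on chromosomes 6 and 9), 6 with the replicate block (Nfu1 to Grm7) and 6 with the block and the dim filter (Aak1 to Cntn6, without Grm7), 4 with array weights (Nfu1 to Magi1), 1 to 3 with 1 array left out (on various chromosomes), 1 without the arrays numbered 1 and 1 at a threshold of 0.01. No called named gene changed sign, whereas uncalled differences of Grm7 probe sets did, and the majority of higher calls between B6By.C and BALB/cJ turned without B6By.C replicate 2 (237 higher, 265 lower). Of the comparisons of single genes, 1054 kept their side of the threshold, 76 lost it and 1 gained it (Grm7, with the block). Gfap, C1qc, C1qb, Cldn5, Maob and Kcnj10 between the parental strains, and Gfap, C1qb, Rgs5, Grin2b, Grik1, Nts, Slc17a7, Kcnj10, Aldh7a1 and Gsr between B6By.C and BALB/cJ, lost their calls without the arrays numbered 1. Fitting only the strains compared lost Cldn5 in the former and Rgs5, Nts, Aldh7a1 and Gsr in the latter. Beyond the members of lists given above (Mal, Nts, Junb, Gsr, Tyrobp, Btg2, Npas4 and Trim30a), the lists it added and Grm7, the replicate block changed no other call of a named gene, list member or list test. The low resolution of dim signal limits comparisons near or below a log2 intensity of 3.968, the median.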

Other observations

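The tests of chance order, of shared arrays and of 3' bias and hybridisation, the runs, and the windows at an unadjusted threshold were chosen after the results were seen; the tests of probe variants, scaling and splits were chosen before. Genes called between the parental strains gathered most densely on chromosome 14, where 10 of 100 consecutive tested genes, from 4933425B07Rik to Myh7, were called, more than the 9 reached in any of 1000 permutations of the calls (permutation p = 0.001, the smallest they can give). Windows of 50 genes reached 6 there (from Wdhd1 to Chd8; permutation p = 0.0802) and windows of 25 genes reached 4, on chromosome 10 (permutation p = 0.563), so only the widest of 3 window sizes stood apart.

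For B6By.C against C57BL/6ByJ, genes with an unadjusted p under 0.01 in limma were placed along the chromosomes. Windows of 100 genes reached 7 such genes on chromosome 6, against at most 6 in 1000 permutations (permutation p = 0.001, the smallest they can give); windows of 50 genes reached 4 there (permutation p = 0.0882), and windows of 25 genes reached 3, on chromosome 1 (permutation p = 0.306). The 7 genes were Gmcl1 (-0.40 ± 0.125, SE, on the log2 scale), the annexin gene Anxa4 (0.33 ± 0.101), Nfu1, which serves iron-sulfur cluster assembly (-0.47 ± 0.118), Chchd4 (-1.02 ± 0.123), the synaptic scaffold gene Magi1 (-0.46 ± 0.114), the mitochondrial S-adenosylmethionine carrier gene Slc25a26 (-0.47 ± 0.109) and Eogt (-0.48 ± 0.122). Nfu1 and Magi1 measured much the same in BALB/cJ against C57BL/6ByJ (-0.49 and -0.46), while Slc25a26 measured -0.12. Without the replicate block those differences of Nfu1 and Magi1 did not pass (limma adjusted p = 0.0922 and 0.108). Both comparisons share the C57BL/6ByJ arrays, which draws their differences together even with no effect. By chromosome, none passed (Fisher's exact test, adjusted p = 0.085 for chromosome 18 and 0.121 for chromosome 6).

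A BALB/cJ-like stretch may lie on chromosome 6 of B6By.C. In the model with the replicate block, 600 genes with a known place were called between the parental strains, 39 of them closer to BALB/cJ in B6By.C, and 6 of these stood next to each other on chromosome 6: Nfu1, Isy1, Chchd4, Frmd4b, Cntn6 and Grm7 (its dimmest probe set), between Nat8f4 and Ogg1, which were not. The median ratio of their B6By.C to BALB/cJ change was 0.924. Chance order of the genes gave no run as long in 10000 permutations (permutation p = 1e-04, the smallest they can give), which reached runs of at most 5. The same permutations, which keep every gene's values, also served for scatter of the shared C57BL/6ByJ arrays. They test only gene order, and so reach that scatter only if it has no order along chromosomes. How such scatter makes a gene look BALB/cJ-like was not tested. Without the block 403 genes were called, and the longest runs were Isy1 with Chchd4 and, on chromosome 9, Nxpe4 with Zw10 (permutation p = 0.0645). The stretch thus depends on that setting. Other bright probe sets of 4 of these genes had a median ratio of -0.0215. This met the bound set beforehand for strain variants under the probes, although the run itself was found after the data were seen. The other probe sets went both ways, with Nfu1 at 1.02, so such variants cannot be told apart from levels. Inheritance of donor DNA there was not tested.

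More probe sets were lower than higher in BALB/cJ (64.4% of 644). Scaling between arrays is argued against, since the lower share was at least 64.3% after median centring or quantile normalization. Strain variants under the probes stay open, because probes that mismatch BALB/cJ sequence could lower its signal with no change in level. Where a gene called lower had another bright probe set (167 genes), the latter moved by a median ratio of 0.107 of the called one (95% bootstrap interval 0.0694 to 0.165). This met the bound set beforehand for strain variants. Higher calls, which this explanation does not need, gave a ratio as low, 0.0526 (0.0117 to 0.13, 104 genes). Meeting the bound therefore does not decide between variants and levels. Among the 47 genes whose other probe sets moved at a ratio over 0.5, 63.8% were lower (exact 95% interval 48.5 to 77.3). A difference in transcript level between the strains was not tested apart from the probes.

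Replicate 1 arrays stood apart from the others of their strain, with 1007 probe sets higher and 436 lower (limma). A 3' bias of the labelled RNA could not be decided: the beta-actin 3' to 5' log2 ratio was higher on replicate 1 in each strain, by at least 0.168, while that of Gapdh was lower, by -0.163, -0.22 and -0.18 in C57BL/6ByJ, BALB/cJ and B6By.C. Hybridisation or scanning stayed open too, as the mean spike signal differed by 0.608, -0.068 and 0.155 in the same order, the latter 2 within the gaps between the other arrays of their strains (0.126 and 0.324). None of the 29 gene lists separated replicate 1 (camera, lowest adjusted p = 0.181). No biological explanation was tested.

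The 6 arrays of a pair of strains can be split in 10 ways, too few for a share under 0.05. BALB/cJ against C57BL/6ByJ gave 644 calls for the real split and at most 0 for the others (1 of 10 as large), B6By.C against BALB/cJ 575 and at most 0 (1 of 10), and B6By.C against C57BL/6ByJ 0 and at most 0 (10 of 10). The other splits that part all pairs of same-numbered arrays also gave 0, but mix the strains.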
